A study of Mus musculus with 18 samples.

How the data were processed

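RNA from brain tissue of mice at postnatal day 7 was measured on 18 Affymetrix arrays, in 6 groups of 3. The labels give a genotype (wild type or knockout), a source and a replicate number for each array, and name TRIZOL extraction of total RNA and the standard Affymetrix labelling protocol. The values came in 3 tables of 6 arrays each. A table for the A chip and a table for the B chip hold cortex samples, with 22626 and 22511 probe sets besides the controls. The remaining table holds samples titled rest, with the source given as P7 brain, on an array of 45037 probe sets. What the word rest covers is not stated, and values were never set across tables as levels.

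The deposited values are intensity values: probe set signals on a linear scale, made by the authors with MAS5, for which no version or setting is given. The arrays of a table had been brought to a near-equal level, since the factors needed here to equalise them lay between 0.9477 and 1.059. Many cells of the tables are blank, from 42% to 46% of an array on the cortex A chip, 57.4% to 66.4% on the B chip and 48.4% to 50.8% in the rest table. The labels do not say why. Probe sets blank on some arrays were dim where listed: on the A chip, those listed on 5 arrays had a median signal of 67.2, against 249 for those listed on all 6. The absent-transcript control (TrpnX) was blank in all of its 18 values in each table.

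Control probe sets were left out. Each array was scaled to a common mean, trimmed by 2% at each end, over the probe sets listed on all 6 arrays of its table, and signals were transformed as log2(signal + 16). The plan had not foreseen blanks. The rule that a probe set is tested when at least 2 arrays of each genotype list it was added after the blanks had been seen, and so was the use of probe sets listed on all 6 arrays for the scaling and the list tests. The planned filter on the mean level, at the 40th percentile of the table with a blank counted as 0, then removed 0 further probe sets in each table. This left 12065 probe sets for the cortex A chip, 7838 for the B chip and 21407 for the rest table. No fold change was computed for a probe set blank throughout one genotype.

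Probe sets were joined to gene symbols through the array annotation, with symbols brought up to date by gene identifier from RefSeq. Those with exactly 1 gene numbered 20380, 14661 and 34945 in the 3 tables; those with several genes (691, 245 and 932) or none were tested but carry no symbol here.

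Knockout was compared with wild type inside each table with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend), with no covariate. P-values were adjusted by Benjamini and Hochberg over the probe sets tested, and a probe set was called at an adjusted p under 0.05. The difference between the cortex A chip and the rest table was tested as an interaction in a joint limma fit of both tables on 11959 shared probe sets. The likeness of the fold changes was measured as a correlation across shared probe sets, which are not independent replicates, and set against 100 pairs of splits of the arrays.

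Before the data were examined, 37 gene lists were fixed: markers of neuronal, glial, vascular, meningeal and blood cells, and genes of damage response, division, stress, synapses, metabolism and signalling. Lists with at least 5 genes were tested with limma's camera at a preset correlation of 0.01, on 1 probe set per gene listed on all 6 arrays (the brightest), with adjustment over the lists. Camera compares a list with all other genes. The same test with an estimated correlation, and fry, which asks whether the genes of a list move on balance one way without comparing them with other genes, were run beside it. Counts of members that passed are given over all probe sets tested and, where stated, adjusted over the list alone.

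The rule for named genes was also fixed before the data were examined. It takes Brca1 in every table. It takes the 8 largest rises and the 8 largest falls among called probe sets with 1 gene symbol and non-overlapping groups in the cortex A chip and the rest table, and 4 each way on the B chip. For a list it takes up to 4 members, those past the threshold with the largest change or else those with the lowest p. For the difference between tables it takes the 5 largest each way. Genes named outside this rule are marked as chosen after their values were seen. Sex-linked genes were read on every array to check the animals. Genes within 10 Mb of Brca1 were compared with all other tested genes by a two-sided Fisher exact test. Measures of array quality were compared by exact two-sided permutation tests, for which 0.1 is the smallest p that 3 arrays against 3 allow.

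The alternatives set in advance were other scalings (none, median centring, quantile normalization), offsets of 1 and 64, no level filter and the 60th percentile, eBayes without a trend and robust eBayes, array weights, a replicate block, leaving out each array, an adjusted p of 0.10, an equal-variance test per probe set, the mean of a gene's probe sets, other list tests, a Spearman correlation, distances of 5 and 20 Mb, and a difference from 2 separate fits. Added after the data were seen were a restriction to probe sets listed on all 6 arrays, blanks set to the 5th percentile of the array's listed signals, the sex-marker pattern of each array as a term (for probe sets listed on knockout replicate 3), and the animal as a random block across tables. The camera test has no robust form, so robust eBayes was not run for the lists. A range of adjusted p given for a list spans all of its alternatives, so its ends may come from fry or from the estimated correlation.

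The fits were tested on simulated data with the sizes and spreads of these tables. Of 50 probe sets given a log2 change of 1, the fit recovered 90% on the A chip, 48% on the B chip and 68% in the rest table; for a log2 change of 2 the shares were 100%, 94% and 98%. The number of arrays limits the precision, with 4 residual degrees of freedom per table. The series record describes the cortices as those of 3 wild-type and 3 knockout animals. Nothing says that the samples titled rest came from separate animals. Sex-linked transcripts differed between the knockout samples of that table (Xist 175.7 in replicate 1 and 3608.5 in replicate 3), so those did not all come from the same animal. For the other samples this is not known. The p-values of that table therefore measure only the spread between these samples, part of which may be technical.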

Results

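Brains of mice lacking Brca1 in the neural lineage were profiled at postnatal day 7. The conditional knockout animals carry a floxed Brca1 allele, with exons 5 to 13 between the recombination sites, over a null allele that has an inverted neo cassette at exon 11, and Cre is expressed from the nestin promoter, which is active in neural progenitors. Cortex was hybridised to an A chip and a B chip, which share few probe sets. A further set of samples, titled rest and with the source given as P7 brain, was hybridised to an array that holds the probe sets of both; what tissue the word covers is not stated. Each of the 3 tables has 3 wild-type and 3 knockout arrays. The arrays listed a signal for 54% to 58% of the probe sets of the A chip, 33.6% to 42.6% of those of the B chip and 49.2% to 51.6% in the rest table, and left the others blank. The mean shares in wild-type and knockout arrays were 55.9% and 56%, 37.4% and 39.1%, and 50.4% and 50.9% (exact two-sided permutation p = 1, 0.6 and 0.7; 0.1 is the smallest possible). The ratio of 3' to 5' actin signal, a measure of RNA integrity, was 1.44 and 1.45 in wild-type and knockout arrays of the A chip, 2 and 2.12 on the B chip and 1.67 and 1.78 in the rest table (exact two-sided permutation p = 1, 0.6 and 0.3). Knockout replicate 3 of the rest table had a ratio of 1.96, against 1.64 to 1.73 on the other 5 arrays. On the B chip, knockout replicate 3 had a ratio of 2.4, against 1.86 to 2.16 on the other 5 arrays. Signals are given as mean ± SD of the scaled signal, with n arrays, and log2 changes as knockout minus wild type with the standard error (SE) of the limma fit. The number of arrays limits the precision.

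The first question was whether the Brca1 transcript was lower. No difference was detected. The Brca1 probe set with a signal on all arrays read 41.3 ± 6.49 in wild-type and 52.2 ± 8.68 in knockout cortex (n = 3 each), a log2 change of 0.25 (SE 0.159, limma adjusted p = 0.496). In the rest table it read 108.9 ± 6.86 and 113.5 ± 24.6 (n = 3 each; log2 change 0.03, SE 0.17, limma adjusted p = 0.978). The remaining Brca1 probe sets were blank on nearly all arrays, and none is on the B chip. The exon that each probe set reads is not given, so these values do not separate an intact transcript from one that lacks the floxed exons. Sex-linked transcripts showed that the genotypes also differ in the animals used. Xist, the transcript of the inactive X chromosome, read 2855.3, 2678.1 and 2849 in the wild-type cortices. In the knockout cortices it read 54.3 in replicate 1, was blank in replicate 2 and read 2178.7 in replicate 3. The Y-linked Eif2s3y was listed only in knockout replicates 1 and 2, at 154.9 and 191.7. The rest table had the same pattern, with Eif2s3y at 257.2 and 237.9 in knockout replicates 1 and 2 only. Genotype is therefore partly joined with sex, and a fit with the sex-marker pattern as a term compares knockout replicate 3, a single array, with the wild type. Probe sets blank on that array have no value in such a fit.

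In the cortex, collagen genes and other genes of mural and meningeal cells rose, and the myelin genes Mbp and Cnp, the interneuron genes Dlx1 and Lhx6 and the neuronal gene Dcx fell. The largest rise on the A chip was that of Itih5, a protein that binds hyaluronan in the extracellular matrix, from 153.3 ± 20.5 to 854.8 ± 65.1 (n = 3 each), 5.16-fold. The collagen gene Col3a1 rose from 436.7 ± 50.3 to 1798 ± 131 and the chemokine gene Cxcl12 from 114 ± 23.7 to 543.1 ± 134 (n = 3 each). Mbp, which encodes a main protein of myelin, fell 9.38-fold, from 1620 ± 246 to 169.2 ± 85.8 (n = 3 each). Dlx1, a transcription factor of interneurons, fell from 219.6 ± 13.4 (n = 3) to 60.4 ± 0.685 (n = 2).

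The log2 changes of these genes were 2.37 for Itih5 (SE 0.111, limma adjusted p = 2.78e-06), 2.01 for Col3a1 (SE 0.0948, adjusted p = 2.78e-06), 2.09 for Cxcl12 (SE 0.189, adjusted p = 0.000175), -3.23 for Mbp (SE 0.252, adjusted p = 6.93e-05) and -1.62 for Dlx1 (SE 0.135, adjusted p = 0.000182). The other large rises were Pcolce (log2 change 1.90), Col1a1 (1.82), Col4a5 (1.80), Slc6a13 (1.79) and Col6a3 (1.61), with limma adjusted p between 2.5e-05 and 0.000872. The other large falls were Ppp1r1b (-1.09), Cnp (-1.07), Rxrg (-1.03), Nxph1 (-1.02), Dcx (-0.996) and Lhx6 (-0.99), with limma adjusted p between 0.00204 and 0.0372. Cnp makes a myelin enzyme, Dcx a microtubule protein of migrating neurons and Lhx6 a transcription factor of interneurons. Some of these calls depended on the setting. With blanks set to a low signal, Ppp1r1b, blank on wild-type replicate 2, had a log2 change of -0.17 (limma adjusted p = 0.934), and Rxrg, blank on that array and on knockout replicate 1, one of -0.64 (limma adjusted p = 0.438). Rxrg also lost its call without a variance trend (0.053) and with a replicate block (0.0984), and changed by -0.68 with an offset of 64. With the sex-marker term Dcx had a log2 change of -0.55 (limma adjusted p = 0.149), and Dlx1 had no value. Col1a1 (1.58, adjusted p = 0.0548), Cnp (-1.14, adjusted p = 0.0509) and Rxrg (-1.26, adjusted p = 0.081) lost their limma call with it but little or none of their change. With that term, 362 of the 364 called probe sets of the A chip had a value, all in the same direction. Knockout replicate 3 had helped to make these calls, so the shared direction is no independent check.

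Of 12065 probe sets tested on the A chip, 364 changed, 278 up and 86 down, and 1899 had an unadjusted p under 0.05. They stand for 215 genes that rose and 58 that fell. More than 2-fold changes numbered 62 up and 12 down. The count was 607 (437 up, 170 down) at an adjusted p of 0.10, 34 (30 up, 4 down) with an equal-variance test per probe set and 82 (63 up, 19 down) with the sex-marker term. It was 218 (181 up, 37 down) without wild-type replicate 1 and 186 (145 up, 41 down) without knockout replicate 2.

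Genes of mural and meningeal cells, which form vessel walls and the coverings of the brain, rose most as a group. Of 27 measured, 21 rose and 0 fell, or 26 rose when adjusted over the list alone. Col3a1, Col1a1, Slc6a13 and Col1a2 (log2 change 1.60) had the largest changes, and the median was 1.07 (camera adjusted p = 1.59e-38; adjusted p = 0.0659 with an estimated correlation). Of 29 endothelial genes 9 rose and 0 fell, or 16 adjusted over the list alone, among them Pltp and Cd34 (both 0.81), with a median of 0.40 (camera adjusted p = 1.86e-11; adjusted p = 0.0659 with an estimated correlation). Of 26 genes of microglia and macrophages 10 rose, among them Mrc1, Ctss (1.01) and C1qa (0.85), and Lpl fell (-0.49). Adjusted over the list alone 15 rose and 1 fell, and the camera adjusted p was 2.22e-10 (adjusted p = 0.138 with an estimated correlation). Of 11 interferon and antigen presentation genes 4 rose and 0 fell, or 7 adjusted over the list alone, led by Ifitm3 (0.90), Ifitm2 (0.81) and B2m (0.70); the camera adjusted p was 2.52e-07 (adjusted p = 0.122 with an estimated correlation).

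Glial reaction and immediate early genes were higher too. Of 17 immediate early genes 5 rose and 0 fell, or 10 adjusted over the list alone, led by Jun (0.84), Klf4 (0.83) and Bdnf (0.78), and the camera adjusted p was 1.02e-06 (adjusted p = 0.138 with an estimated correlation). Of 17 genes of reactive astrocytes 6 rose, among them Gfap (0.90), Vim (0.76) and Srgn (0.69), and B3gnt5 fell; adjusted over the list alone 12 rose and 1 fell (camera adjusted p = 1.39e-06; adjusted p = 0.138 with an estimated correlation). Of 30 astrocyte genes 6 rose and 0 fell, or 10 adjusted over the list alone, among them the water channel gene Aqp4 (1.03), from 349.9 ± 53.6 to 727.9 ± 75.3 (n = 3 each). The camera adjusted p of that list was 0.000965 (adjusted p = 0.356 with an estimated correlation), and 0.134 with the sex-marker term (range 9.73e-05 to 0.356). Of 9 choroid plexus genes only Igfbp2 (0.69), which is also on the mural and meningeal list, rose, or 6 adjusted over the list alone (camera adjusted p = 0.00101; adjusted p = 0.327 with an estimated correlation). Of 31 heat shock and stress response genes Slc3a2 (0.28) rose, with 0 adjusted over the list alone. That list was called by camera (adjusted p = 0.0194; adjusted p = 0.158 with an estimated correlation) and was not called without wild-type replicate 1 (0.0561) or with the sex-marker term (0.134; range over its 22 alternatives 0.00455 to 0.158).

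The neuronal lists called on the A chip moved down, except deep-layer cortical neurons. Of 17 upper-layer genes 0 rose and 2 fell, Pou3f1 (-0.56) and Mef2c (-0.47); adjusted over the list alone 1 rose and 8 fell (camera adjusted p = 0.000521; adjusted p = 0.122 with an estimated correlation). Of 21 deep-layer genes Ccn2 rose (1.10), or 4 adjusted over the list alone, and the median was 0.28 (camera adjusted p = 0.000841; adjusted p = 0.284 with an estimated correlation). Of 17 GABA synapse genes Gad1 fell (-0.68) and Slc6a13, which is also on the mural and meningeal list, rose, or 4 fell and 1 rose adjusted over the list alone. Its camera adjusted p was 0.0046 (adjusted p = 0.284 with an estimated correlation), and 0.106 without wild-type replicate 3 (range over its alternatives 0.000311 to 0.284). Of 18 pan-cortical excitatory genes 4 fell and 0 rose, Neurod1 (-0.98), Bcl11a (-0.54), Mef2c and Satb1 (-0.38), or 6 adjusted over the list alone (camera adjusted p = 0.0229; adjusted p = 0.405 with an estimated correlation). That call was lost without wild-type replicate 1 (0.11), wild-type replicate 2 (0.0804), knockout replicate 1 (0.0679) or knockout replicate 2 (0.0781), without a variance trend (0.0565) and with the sex-marker term (0.607; range 0.00168 to 0.607). Of 29 glutamatergic synapse genes Gria1 fell (-0.50) and Nptx1 rose (0.73), with 2 each way adjusted over the list alone (camera adjusted p = 0.0229; adjusted p = 0.284 with an estimated correlation). It was lost without wild-type replicate 1 (0.0561), wild-type replicate 3 (0.0684) or knockout replicate 2 (0.134), and with the sex-marker term (0.253; range 0.0105 to 0.284). Of 19 genes of oligodendrocyte precursors Olig1 (-0.50) and C1ql1 (-0.66) fell and Dcn, which is also on the mural and meningeal list, rose (1.25), or 5 fell and 1 rose adjusted over the list alone. The camera adjusted p was 0.0229 (adjusted p = 0.355 with an estimated correlation), 0.0674 without wild-type replicate 1 and 0.28 with a filter at the 60th percentile (range 0.00612 to 0.355).

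Myelin genes split. Of 19 measured, Mbp, Cnp, Ugt8a (-0.99), Tspan2 and Sirt2 fell and Lpar1 rose (1.31), or 7 fell and 4 rose adjusted over the list alone. The median log2 change of the list was 0.12, its mean was -0.15 and camera gave the direction down, with an adjusted p of 0.808. Of 15 genes of cortical interneurons Dlx1, Lhx6, Gad1 and Satb1 fell and Nr2f2 rose (0.87), or 6 fell and 3 rose adjusted over the list alone. The interneuron list was not called (camera adjusted p = 0.146), but was without knockout replicate 2 (0.0389), with the sex-marker term (0.00429) and with blanks set to a low signal (0.000342; range 0.000342 to 0.566). Of 11 striatal genes Ppp1r1b and Rxrg fell; the list had a camera adjusted p of 0.235, 6.52e-05 without wild-type replicate 2 and 0.0302 with blanks set to a low signal (range 6.52e-05 to 0.752). Of 24 Wnt, Shh and Notch pathway genes 6 rose, among them Bmp7 (1.25) and Wnt5a (1.03), or 8 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0841). Camera called the pathway list without wild-type replicate 3 (0.0465) or knockout replicate 1 (0.0297), with a filter at the 60th percentile (0.00485) and with blanks set to a low signal (0.0264). It was also called by fry (adjusted p = 0.00863), and its adjusted p over all alternatives ranged from 0.00485 to 0.284.

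The lists closest to the known function of Brca1 were not called in the cortex, though some were under other settings. Only part of each list was measured. The shares were 19 of 50 genes for double-strand break repair and checkpoints, 20 of 38 for p53 targets and 17 of 38 for microcephaly and centrosome genes. For cell cycle genes it was 29 of 51 and for apoptosis genes 24 of 32. Members that were not measured are not covered by these results. Of 19 genes of double-strand break repair and checkpoints 0 passed, with 0 adjusted over the list alone and 2 at an unadjusted p under 0.05 in limma, and the median log2 change was -0.02, while the mean was 0.01 and camera gave the direction up (adjusted p = 0.808). Of 20 p53 targets 0 passed, 4 adjusted over the list alone and 6 at an unadjusted limma p under 0.05 (camera adjusted p = 0.295, and 0.0493 with blanks set to a low signal; range 0.0493 to 0.655). Of 17 microcephaly and centrosome genes 0 passed, 0 adjusted over the list alone and 3 at an unadjusted limma p under 0.05 (camera adjusted p = 0.808). Among 29 cell cycle genes Ccnd1 rose (0.48), with 5 adjusted over the list alone; the camera adjusted p was 0.097, 0.00682 without wild-type replicate 3, 0.0372 with the mean of a gene's probe sets and 0.044 with blanks set to a low signal (range 0.00682 to 0.655). Among 24 apoptosis genes Casp8 rose (0.64), with 1 adjusted over the list alone (camera adjusted p = 0.654). Among 34 lists tested on the A chip, camera with the preset correlation called 10 up and 5 down. With the estimated correlation camera called 0, with 8 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0659, while fry called 9. Of those 9, 8 were also called by camera with the preset correlation, and the other was the Wnt, Shh and Notch list. Other splits of the 6 arrays called up to 11 lists.

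**Figure D1:**
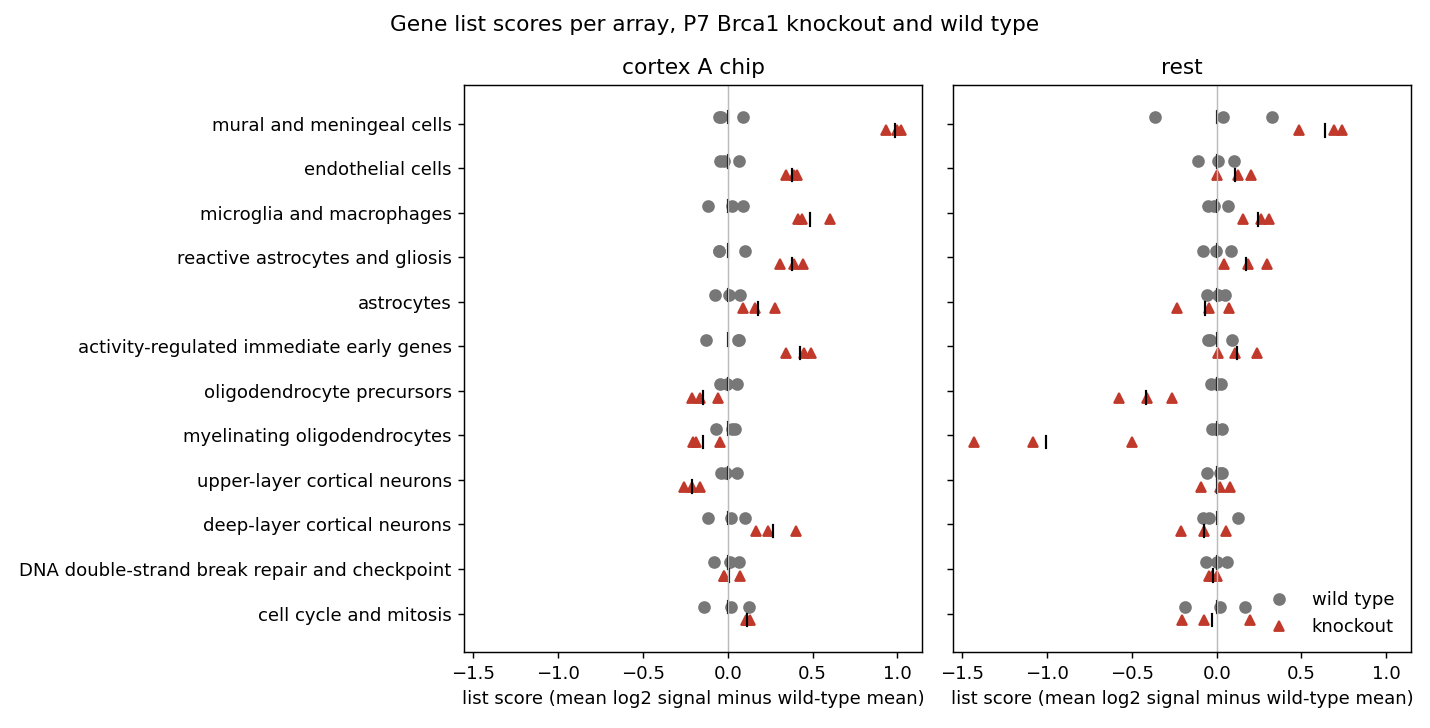
Each point is the score of an array for a gene list, the mean log2 signal of its measured genes minus the mean of the wild-type arrays, for 12 lists in the cortex A chip and the rest table; circles are wild type, triangles are knockout and bars are group means. The 3 knockout arrays lie above all wild-type arrays for mural and meningeal genes in both tables, where the median gene changed by 1.07 in the cortex and 0.63 in the rest table.

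The B chip reads other probe sets of the cortex samples. Tbx18, a transcription factor of mural and meningeal cells, rose from 171.8 ± 20.7 to 862 ± 52 (n = 3 each), a log2 change of 2.23 (SE 0.162, limma adjusted p = 1.1e-05). Gpr17, a receptor of oligodendrocyte precursors, fell from 1191 ± 122 (n = 3) to 374.1 ± 54.2 (n = 2), a log2 change of -1.63 (SE 0.168, limma adjusted p = 0.000802). The myelin gene Bcas1 fell from 1650 ± 231 to 595.6 ± 238 (n = 3 each). Kank2 (1.79), Tmem64 (1.52) and Ranbp3l (1.48) also rose, with limma adjusted p between 0.000802 and 0.00465. Gpr6 (-1.11) and Vezt (-0.82) also fell, each with a limma adjusted p of 0.0454 and a call lost in 9 of 20 alternatives, among them the fits without a variance trend (0.082 and 0.148) and with a replicate block (0.0556 and 0.0791). Of 5 choroid plexus genes on the B chip, too few for a list test, Kcnj13 (1.25, limma adjusted p = 0.0414) and Sulf1 (1.07, limma adjusted p = 0.00661) rose, and Ttr (1.33, limma adjusted p = 0.178) did not pass. Bcas1 lost its call without a variance trend (0.0917) and without wild-type replicate 3 (0.0599). Of 7838 probe sets 22 changed, 18 up and 4 down, and 579 had an unadjusted p under 0.05. The count was 9 without a variance trend, 66 (54 up, 12 down) with array weights, 12 with a replicate block and 48 (40 up, 8 down) at an adjusted p of 0.10. With the sex-marker term, 21 of the 22 called probe sets had a value, all in the same direction, but knockout replicate 3 had helped to make these calls. With blanks set to a low signal the count was 5, and with an equal-variance test per probe set 0. It was 11 without wild-type replicate 1, 13 without wild-type replicate 2 and 9 without knockout replicate 2. Of the 8 genes named here for the B chip, only Tbx18 kept its call with blanks set to a low signal, and Gpr17 had no value with the sex-marker term. Of 18 lists tested, camera with the preset correlation called 2 up, those of Wnt, Shh and Notch genes (adjusted p = 0.00565; 0.228 with an estimated correlation) and immediate early genes (0.0181; 0.252). It called 3 down, those of striatal neurons (0.000565; 0.445), upper-layer neurons (0.00325; 0.228) and neuronal migration (0.013; 0.228). The striatal scores per array overlapped between the genotypes, at 0.25, -0.391 and 0.141 in wild type and -0.319, -0.456 and -0.442 in knockout. Wild-type replicate 2 also had the lowest striatal score of the A chip arrays (-0.468). The Wnt, striatal and migration lists were not called on the A chip (camera adjusted p = 0.0841, 0.235 and 0.129). Of the neuronal lists called on the A chip, deep-layer genes (median -0.02, camera adjusted p = 0.945), GABA synapse genes (0.73), glutamatergic synapse genes (0.97, direction up) and pan-cortical excitatory genes (0.688) were not called on the B chip. They had 0 genes passed in limma there, with 4, 0, 5 and 2 at an unadjusted p under 0.05. The list of oligodendrocyte precursors was not called on the B chip either (0.706). The B chip lists were not run with other settings of the fit. With the estimated correlation camera called 0 on the B chip, with 3 at an unadjusted p under 0.05 and a lowest adjusted p of 0.228, and fry called 2.

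In the samples titled rest, 8 of 27 myelin genes fell and 7 of 33 mural and meningeal genes rose; both lists were called, and neither with an estimated correlation (adjusted p = 0.71 for each). Mal, a myelin membrane protein, fell 5.02-fold, from 474.8 ± 25.6 to 87.9 ± 45.8 (n = 3 each). Galc, an enzyme that breaks down a myelin lipid, fell from 192.6 ± 5.44 to 52.4 ± 12.1, and Cnp from 2818 ± 131 to 935.6 ± 475 (n = 3 each). Tgfbi, an adhesion protein of the extracellular matrix, rose 4.68-fold, from 89.6 ± 19.6 to 480.7 ± 110, and Itih5 rose from 429.3 ± 50.6 to 1199 ± 40.6 (n = 3 each).

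The log2 changes were -2.33 for Mal (SE 0.253, limma adjusted p = 0.00835), -1.62 for Galc (SE 0.159, adjusted p = 0.00507), 2.23 for Tgfbi (SE 0.186, adjusted p = 0.00411) and 1.45 for Itih5 (SE 0.0959, adjusted p = 0.0011). The other large rises were Tbx18 (2.09), Slc6a13 (1.73), Cxcl12 (1.56), Lama1 (1.54), Col3a1 (1.40) and Lum (1.30), with limma adjusted p between 0.00507 and 0.0394. The other large falls were Gpr17 (-2.06), Fa2h (-2.04), Cnp (-1.69), Gsn (-1.66), Adamts4 (-1.55) and Pllp (-1.48), with limma adjusted p between 0.0157 and 0.0377. With the sex-marker term all 16 genes kept their direction, while only Itih5 and Mal kept their call. The rises held most of their size, as in Tgfbi (2.16), Tbx18 (2.10), Slc6a13 (1.96), Lama1 (1.53), Col3a1 (1.44) and Lum (1.36), and the falls became smaller, between -1.66 for Mal and -0.91 for Gsn (limma adjusted p = 0.104), with Cnp at -0.93 (limma adjusted p = 0.0908). All 67 called probe sets of the rest table kept their direction with that term. Knockout replicate 3 had helped to make these calls, and the 16 genes were chosen for groups that do not overlap. The shared direction is therefore no independent check. Calls were kept for 5 of the 16 without a variance trend, 11 with robust eBayes and 10 with blanks set to a low signal. They were kept for 11 without wild-type replicate 1, 10 without wild-type replicate 2, 11 without wild-type replicate 3, 9 without knockout replicate 1, 5 without knockout replicate 2 and 12 without knockout replicate 3. Mbp, chosen after its values were seen, read 6345 ± 429 and 1962 ± 2040 (n = 3 each) and did not pass (log2 change -2.46, limma adjusted p = 0.289). Of 21407 probe sets 67 changed, 31 up and 36 down, and 2250 had an unadjusted p under 0.05. They stand for 22 genes that rose and 28 that fell. The count was 11 (7 up, 4 down) without a variance trend, 143 (44 up, 99 down) with a replicate block, 161 (57 up, 104 down) at an adjusted p of 0.10, 0 with an equal-variance test per probe set and 10 (2 up, 8 down) with the sex-marker term. It was 40 (27 up, 13 down) without wild-type replicate 1, 30 (20 up, 10 down) without wild-type replicate 2, 27 (12 up, 15 down) without knockout replicate 1 and 13 (8 up, 5 down) without knockout replicate 2.

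Of 27 myelin genes measured in the rest table, 8 fell and 0 rose, among them Mal, Fa2h, Cnp and Gsn, or 22 fell and 2 rose adjusted over the list alone, with a median of -0.75 (camera adjusted p = 2.24e-18; adjusted p = 0.71 with an estimated correlation). Of 27 genes of oligodendrocyte precursors Gpr17, Sox10 (-1.10), Olig2 (-1.05) and Vxn (-0.85) fell and Dcn, which is also on the mural and meningeal list, rose (0.96), or 11 fell and 1 rose adjusted over the list alone (camera adjusted p = 3.45e-12; adjusted p = 0.653 with an estimated correlation). Of 33 mural and meningeal genes 7 rose and 0 fell, among them Tbx18, Slc6a13, Col3a1 and Lum, or 18 adjusted over the list alone, with a median of 0.63 (camera adjusted p = 8.65e-17; adjusted p = 0.71 with an estimated correlation). The score of this list per array spread widely in wild type, at 0.328, -0.363 and 0.0347. The knockout arrays scored 0.483, 0.691 and 0.738. Of 28 genes of microglia and macrophages 0 passed in limma, 5 adjusted over the list alone and 10 at an unadjusted p under 0.05 (camera adjusted p = 3.04e-06; adjusted p = 0.653 with an estimated correlation). C1qb had a log2 change of 0.65 (limma adjusted p = 0.0943). Of 20 cerebellar granule cell genes Chn2 fell (-0.91), and the camera adjusted p of the list, called down, was 9.11e-05 (adjusted p = 0.728 with an estimated correlation) and 0.0776 without wild-type replicate 3 (range 2.42e-09 to 0.728).

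Smaller calls in the rest table depended on single arrays. The list of reactive astrocytes was called up with 0 of 22 genes passed in limma, 1 adjusted over the list alone and 8 at an unadjusted p under 0.05 (camera adjusted p = 0.0101; adjusted p = 0.728 with an estimated correlation; 0.163 without knockout replicate 3; range 2.94e-05 to 0.728). Among 23 p53 targets Dcxr rose (1.27), or 6 rose and 2 fell adjusted over the list alone, and the list was called up (camera adjusted p = 0.0299; adjusted p = 0.728 with an estimated correlation; 0.124 without knockout replicate 3; range 0.00445 to 0.728). The pan-cortical excitatory list was called down with 0 of 24 genes passed in limma, 0 adjusted over the list alone and 5 at an unadjusted p under 0.05 (camera adjusted p = 0.0317; adjusted p = 0.728 with an estimated correlation). Its adjusted p was 0.628 without wild-type replicate 2, 0.231 without knockout replicate 2, 0.165 without knockout replicate 3, 0.0605 without a variance trend and 0.0537 with blanks set to a low signal (range 4.25e-05 to 0.762). The endothelial list was called up with 0 of 33 genes passed in limma, 0 adjusted over the list alone and 7 at an unadjusted p under 0.05 (camera adjusted p = 0.0321; adjusted p = 0.728 with an estimated correlation). Its adjusted p was 0.441 without wild-type replicate 2, 0.0524 without knockout replicate 1, 0.386 without knockout replicate 3, 0.112 with array weights and 0.0537 with blanks set to a low signal (range 0.000247 to 0.728). Double-strand break repair (34 of 50 genes measured, camera adjusted p = 0.583) and cell cycle genes (40 of 51, camera adjusted p = 0.591) were not called. Apoptosis (26 of 32, camera adjusted p = 0.536) and microcephaly genes (25 of 38, camera adjusted p = 0.941) were not called either. These lists had 0 genes passed in limma, with 1, 3, 2 and 2 at an unadjusted p under 0.05. The apoptosis list had a median of 0.02, a mean of -0.02 and the direction down. Some lists just short of the threshold gained a call elsewhere. The astrocyte list (down, camera adjusted p = 0.0508) was called in 8 of 22 alternatives, and the olfactory bulb list (down, 0.0514) in 10 of 22. Neural progenitor genes (down, 0.0578) and interferon genes (up, 0.0606) were each called in 6 of 22. The cell cycle list of the rest table was called down without wild-type replicate 2 (0.0137) or knockout replicate 3 (0.0199), and up with the sex-marker term (0.00301; range 0.00301 to 0.936). Among 36 lists tested in the rest table camera with the preset correlation called 5 up and 4 down. With the estimated correlation camera called 0, with 2 at an unadjusted p under 0.05 and a lowest adjusted p of 0.653, and fry called 0, with a lowest adjusted p of 0.194. Other splits of the 6 arrays called up to 14 lists, more than the 9 of the genotypes.

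**Figure D2:**
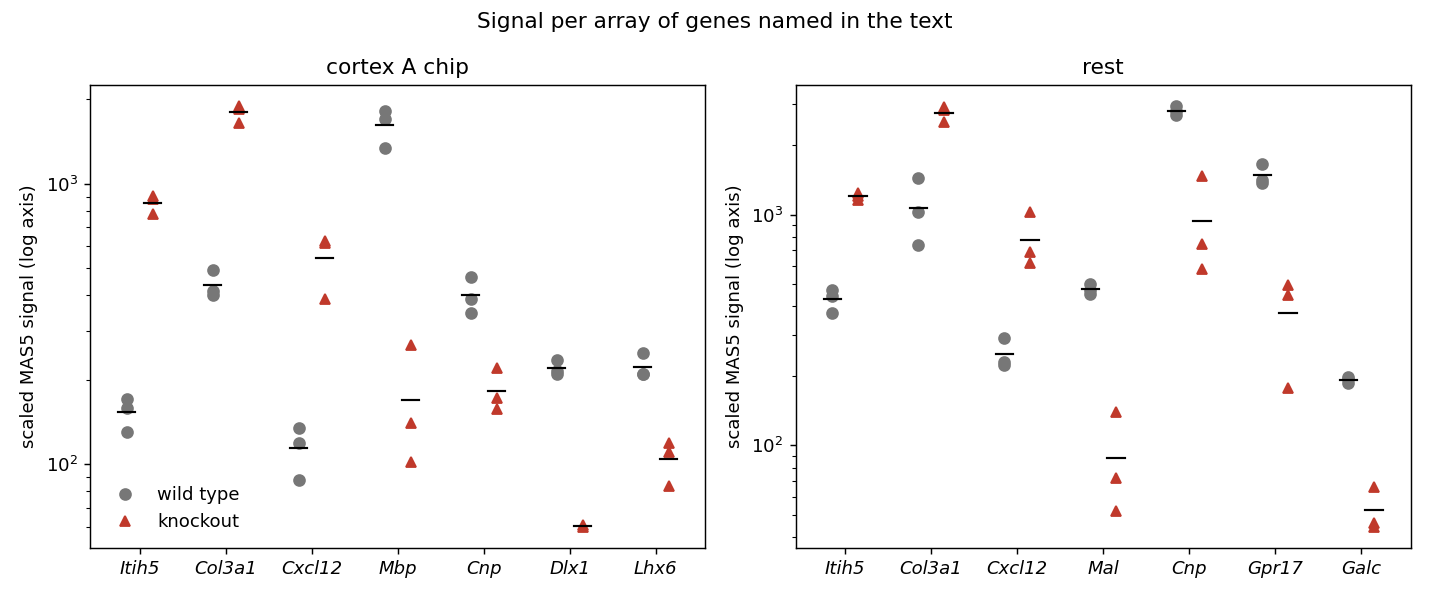
Scaled signal on a log axis for genes of the cortex A chip and the rest table; each point is an array, circles are wild type, triangles are knockout and black bars are group means. Itih5 rises from a mean of 153.3 to 854.8 in the cortex and from 429.3 to 1199 in the rest table, and Mbp falls from 1620 to 169.2 in the cortex.

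The cortex and the rest table changed partly alike. Across 11959 shared probe sets, which are not independent replicates, the log2 changes had a Pearson correlation of 0.369 and a Spearman correlation of 0.19. Of 100 pairs of splits of the arrays, 1 gave a Pearson correlation as large, the real one, and the highest other was 0.27. The same 25 probe sets were called in both, 19 up and 6 down, where calls independent between the tables would give 0.46 and 0.18. They stand for 15 genes that rose, among them Itih5, Col3a1, Cxcl12 and Tgfbi, and 5 that fell, Dcx, Cnp, Sirt2, Tspan2 and Chn2. Of the cortex calls 82.9% had the same direction in the rest table, against 54.8% of all shared probe sets. The labels do not say whether both tables come from the same animals. The sex-marker pattern is the same in both, so differences of animals or sex could also give shared calls, which the expected counts do not allow for.

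A difference of the knockout effect between the tables was called for 6 of 11959 probe sets, with 1257 at an unadjusted p under 0.05. Lpar1, a receptor for lysophosphatidic acid, changed by 1.31 in the cortex and -0.56 in the rest table, a difference of -1.87 (SE 0.217, limma adjusted p = 0.0051). For Gsn, an actin-severing protein, the changes were 0.16 and -1.28 at one probe set (adjusted p = 0.0051) and 0.29 and -1.37 at another (adjusted p = 0.00709). Lgals1 changed by 1.49 and 0.64 and Tmtc4 by -0.80 and 0.02, and Malat1 had a difference of -1.56; each had a limma adjusted p of 0.035. The array type cancels from such a difference only if both arrays respond alike. The count was 3 with an offset of 64, 1 with a filter at the 60th percentile, 3 without a variance trend, 11 with array weights, 16 with blanks set to a low signal, and 0 from separate fits or with the sex-marker term. It was 0 without wild-type replicate 1 or wild-type replicate 3, 13 without wild-type replicate 2, 1 without knockout replicate 1 or knockout replicate 2, and 11 without knockout replicate 3.

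**Figure D3:**
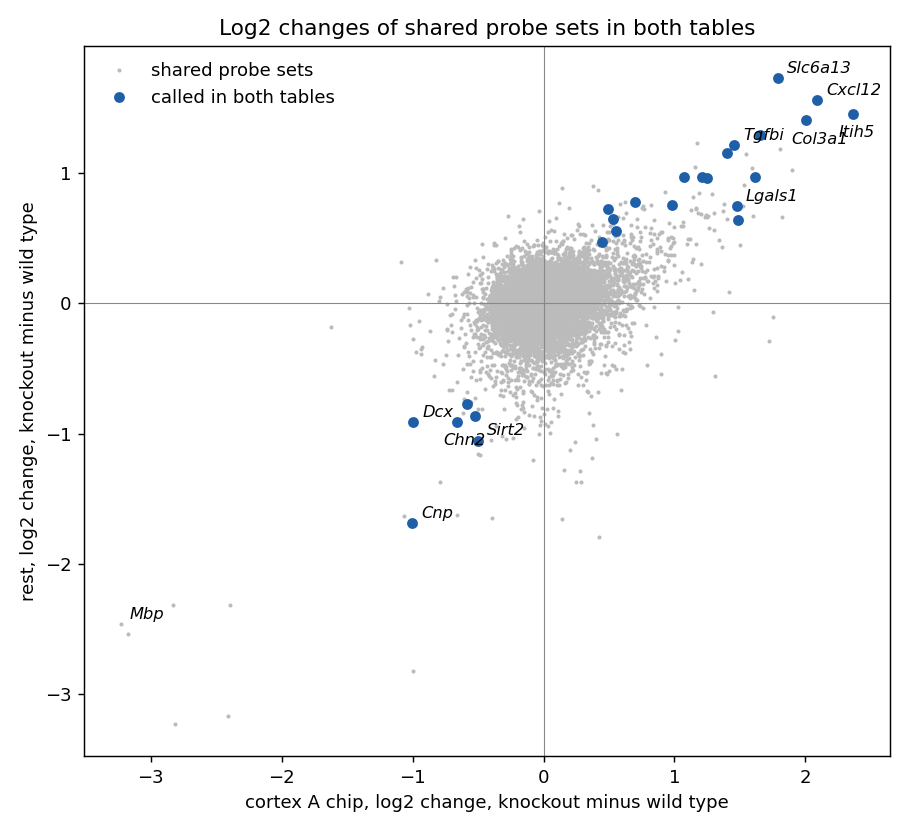
Log2 change (knockout minus wild type) in the rest table against that in the cortex A chip for 11959 shared probe sets; blue points are the 25 called in both tables. The blue points lie on the same side of 0 in both tables, and the Pearson correlation of all points is 0.369.

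A targeted locus carries linked genes of the strain in which it was made, so genes near Brca1 on chromosome 11 were set against all others. In the cortex 11 of 145 genes within 10 Mb changed (7.59%), against 262 of 7122 others (3.68%), an odds ratio of 2.15 (95% interval 1.03 to 4.03, two-sided Fisher exact p = 0.024). The 11 are Ramp2, Cnp, Igfbp4, C1ql1, Col1a1, Cavin1, Mapt, Gfap, Grn, Smarcd2 and Ppp1r1b. Within 5 Mb, 10 of 101 genes changed (9.9%), an odds ratio of 2.88 (95% interval 1.32 to 5.63, two-sided Fisher exact p = 0.00447). By the same exact test, the call was lost without wild-type replicate 1 (odds ratio 1.95, p = 0.139), wild-type replicate 3 (1.65, p = 0.165), knockout replicate 1 (1.98, p = 0.0741) or knockout replicate 2 (2.24, p = 0.0619), and at 20 Mb (1.3, p = 0.33). By that exact test it was kept without wild-type replicate 2 (3.31, p = 0.000657), without knockout replicate 3 (2.38, p = 0.0193) and with the sex-marker term (3.27, p = 0.041). By the exact test it was also lost with a filter at the 60th percentile (1.91, p = 0.0975), without a variance trend (1.86, p = 0.102), with array weights (1.97, p = 0.0506), with a replicate block (1.92, p = 0.0812), on probe sets listed on all 6 arrays (1.77, p = 0.112) and with blanks set to a low signal (1.70, p = 0.157). The p over its alternatives ranged from 0.000657 to 0.33. In the rest table, 2 of 211 genes changed (0.948%), Cnp and Igfbp4, an odds ratio of 2.16 (95% interval 0.252 to 8.32, two-sided Fisher exact p = 0.247).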

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

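The limma test of the difference between tables was planned, and the tests of explanations in this part, the splits of the arrays included, were chosen only after the results were seen. A knockout effect that differs between the cortex A chip and the rest table was called for 6 probe sets, and the genes are Lpar1 (rest minus cortex -1.87), Gsn (-1.44 and -1.65), Lgals1 (-0.85), Malat1 (-1.56) and Tmtc4 (0.82). Of 100 drawn pairs of splits, 8 gave as many calls, the real pair included. Another 5 of the 8 have the genotype split in one table and 1 has it in both with the sides of one table turned, so these carry the genotype effect and do not measure chance; the turned pair gave the highest count, 445. Among the 77 pairs with the genotype split in neither table, 1 gave as many, with 7 calls. Whether chance gives 6 calls is left open by these pairs. At the level of lists, in a comparison that was not planned, camera with an estimated correlation called 0 of 34, with 4 at an unadjusted p under 0.05 and a lowest adjusted p of 0.27. With the preset correlation it called 13, 12 lower in the rest table than in the cortex and 1, GABA synapse genes, higher. The lists share genes, and splits of the arrays were not run for this comparison. No explanation of these differences was tested.

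The mural and meningeal list was called up in both tables, with 21 of 27 genes passed in the cortex and 7 of 33 in the rest table, but in neither with an estimated correlation (adjusted p = 0.0659 and 0.71). A lower share of the main cell type would raise the markers of other types alike, provided that none of those types was lost too. The mean change of the meningeal list exceeded that of the astrocyte list by 0.807 (SE 0.0441) in the cortex and by 0.706 (SE 0.17) in the rest table. This argues only against a loss that spares astrocytes. Cre was expressed in neural progenitors, so astrocytes may have been affected along with neurons. A lower share of neural cells as a whole is left open, and on scaled arrays it would look like a larger share of meningeal cells. A larger share of meningeal and vessel-wall cells would raise list members other than matrix genes too. Their mean change was 0.784 (SE 0.054; 10 of 10 higher) in the cortex and 0.579 (SE 0.19; 11 of 14 higher) in the rest table, against 1.12 and 0.689 for the matrix genes. These members are part of the list that had already been called up, so their rise was largely known beforehand and cannot decide the question. A larger share of such cells, whether from dissection or in the tissue, is left open. Sex stays open, since the knockout array with the wild-type sex-marker pattern scored 0.934 in the cortex (other knockout arrays 1.01, wild-type SD 0.0802), and 1 array excludes nothing.

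The myelin list was called down in the rest table, with 8 of 27 genes passed in limma. It was not called there with an estimated correlation (camera adjusted p = 0.71) or with fry (adjusted p = 0.22). In the cortex Mbp, Cnp, Ugt8a, Sirt2 and Tspan2 fell, Lpar1 rose and the list was not called (camera adjusted p = 0.808). If tissue rich in myelin had been moved from the part behind one table to the other, the genes that fell in the cortex would be higher in the rest table. Their mean change there was -1.78 (SE 0.571), so moved tissue alone does not account for lower values in both tables. The fall of myelin genes in the rest table was known before this test was chosen. Such a fall could hide the effect of moved tissue, so a part of it in the cortex change is left open. Sex is not separated from genotype here either: the knockout array with the wild-type sex-marker pattern scored -0.499 in the rest table, between the wild-type arrays (SD 0.0297) and the other knockout arrays (-1.25). That array also had the highest ratio of 3' to 5' actin signal of the rest table, 1.96 against 1.64 to 1.73, so its score cannot be put down to sex alone. Fewer or less mature oligodendrocytes in the knockout remain a possible explanation that these data leave untested.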

How the results depend on the processing

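The alternatives that were chosen only after the data were seen are the restriction to probe sets listed on all 6 arrays, blanks set to a low signal (the 5th percentile), the sex-marker term and the animal as a random block. The list results that turned were cell cycle genes and choroid plexus genes in the rest table, not called before and called the opposite way with the sex-marker term (up at an adjusted p of 0.00301, and down at 0.00936). A sign also changed with no call on either side in 16 list values of the cortex, 46 list values of the rest table and 4 values of Brca1 in the rest table. The cause of the changes given here was not tested, except that leaving out an array leaves fewer samples and a looser threshold passes more.

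The count of changed probe sets on the A chip (364) was 607 at an adjusted p of 0.10, 34 with the equal-variance test, 82 with the sex-marker term, and 186 to 327 without single arrays. On the B chip (22) it was 9 without a trend, 66 with array weights, 12 with the replicate block, 48 at 0.10, 0 with the equal-variance test, 5 with blanks set low, and 9 to 25 without single arrays. In the rest table (67) it was 11 without a trend, 143 with the replicate block, 161 at 0.10, 0 with the equal-variance test, 10 with the sex-marker term, and 13 to 68 without single arrays. The block rests on equal replicate numbers, which the labels do not describe as pairs. On the B chip, correlations across probe sets between the genotypes were higher at equal numbers (0.152, 0.0685 and 0.159) than at other numbers (highest 0.000456). In the rest table this held for replicate 3 (0.24 against -0.0998) but not for replicates 1 and 2, and on the A chip only for replicate 2 (0.0176 against 0.0104). Whether arrays of equal number share a batch was not tested, and the main fit has no term for it. The count of differences between tables (6) was 3 with an offset of 64, 1 at the 60th percentile, 3 without a trend, 11 with array weights, 0 from separate fits, 0 with the sex-marker term, 16 with blanks set low, and 0 to 13 without single arrays.

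The correlation between tables (0.369) was 0.429 at the 60th percentile, 0.191 as Spearman, 0.323 with the sex-marker term and 0.266 to 0.385 without single arrays. Lists called in the cortex (15) were 0 with the estimated correlation, 9 with fry and 11 to 16 without single arrays. Lists called in the rest table (9) were 0 with the estimated correlation, 0 with fry, 16 with the sex-marker term and 9 to 12 without single arrays. The odds ratio near Brca1 in the cortex (2.15) was 1.91 at the 60th percentile, 1.86 without a trend, 1.97 with array weights, 1.92 with the replicate block, 2.88 at 5 Mb, 1.3 at 20 Mb, 1.77 on probe sets listed on all 6 arrays, 1.70 with blanks set low and 1.65 to 3.31 without single arrays.

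Of the 40 calls of named genes, 25 passed without a trend, 18 with the sex-marker term, 25 with blanks set low and 24 to 33 without single arrays. The sex-marker term gave a value to 38 of them, all in the same direction, with a median ratio of log2 changes of 0.985. It leaves 1 knockout array to compare. The named genes were chosen for groups that do not overlap. That array therefore lay beyond every wild-type array, and the direction was fixed in advance. Over 776 values of single named genes 670 stayed on their side of the threshold and 106 fell short of it. For lists the counts were 693 of 747 in the cortex (38 weaker, 16 stronger) and 717 of 792 in the rest table (31 weaker, 42 stronger, 2 turned). Brca1 was not called under any alternative run, with adjusted p between 0.401 and 0.733 in the cortex and between 0.849 and 0.994 in the rest table; the 60th percentile filter removed it from the A chip. Robust eBayes was not run for the lists. Signal over background limits the dim probe sets: those listed on 5 arrays had a median signal of 67.2 on the A chip, against 249 for those listed on all 6.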

Other observations

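All tests in this part were chosen only after the results were seen. Some probe sets were listed on all 3 arrays of one genotype and on none of the other, so they have no fold change and are not among the calls. The genes named here were chosen after their values were seen. On the cortex A chip, a probe set of Cyp1b1 was listed only in knockout arrays, at 262 ± 30.5, and so was a probe set of Aldh1a1, at 165 ± 11.7 (mean ± SD, n = 3 each). Probe sets listed only in wild-type arrays of that chip included those of the interneuron peptide gene Vip, at 179.4 ± 48.7, and the myelin gene Mag, at 95.1 ± 5.7 (n = 3 each). In the rest table a probe set of Plxnb3 (215.1 ± 10) and a probe set of the myelin regulator Myrf (187.9 ± 55.4) were listed only in wild-type arrays (n = 3 each). A blank does not show that a transcript is absent. In the rest table a probe set of Col4a1 was listed only in knockout arrays, at 1232 ± 199, while another probe set of Col4a1 read 1170 ± 195 in wild-type and 2293 ± 267 in knockout arrays (n = 3 each).

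Such probe sets numbered 65 in knockout and 43 in wild type on the A chip, 108 in all, against 36 to 71 for other splits of the arrays. On the B chip there were 69 (55 and 14), where another split gave 212, so the genotype split does not stand out there. Both replicate 3 arrays of that chip listed the fewest probe sets. The shares were 34.5% in wild type and 33.6% in knockout, against 38.2% to 42.6% on the others. Whether this underlies the 212 was not tested. In the rest table the probe sets listed in a single genotype numbered 198 (118 and 80), against 90 to 134 for other splits. The per-array scores of gene lists did not overlap between genotypes for 17 of 34 lists in the cortex and 8 of 36 in the rest table. Chance gives 10%, and the highest of the other splits was 5 and 6.

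The 6 arrays of a table make 10 splits, so no share under 0.1 can be had. The genotype split, 1 of the 10, gave 364 changed probe sets on the A chip, where the highest other gave 2. The counts were 22 and 0 on the B chip and 67 and 2 in the rest table. On the A chip 15 lists were called, where the highest other split gave 11. In the rest samples, 9 lists were called, 7 of 10 splits called as many, and the highest other gave 14. With both tables split alike the correlation of changes was 0.369, and the highest other was 0.258.

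Linked variants of the targeting strain may underlie the higher share of changed genes near Brca1 in the cortex. Of the 11 genes, 6 belong to a gene list. Outside the lists 5 of 129 genes near Brca1 changed, against 171 of 6474 others (odds ratio 1.49, 95% interval 0.468 to 3.63, two-sided Fisher exact p = 0.397), which leaves this open. The odds ratio over all genes was higher within 5 Mb (2.88) and lower within 20 Mb (1.3) than within 10 Mb (2.15), and linked variants remain open.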
